A study of Mus musculus with 17 samples.

How the data were processed

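The series follows mouse bone marrow cells as they become osteoclasts, the multinucleated cells that dissolve bone. Per the labels' protocols, marrow of 8-week-old C57BL/6 mice was grown with M-CSF, a growth factor for macrophages, for 2 days, and then with RANKL, the cytokine that drives osteoclast formation, together with M-CSF. Cells were taken at day 0 (before RANKL), day 1 (24 hours) and day 3 (72 hours) from collagen-coated dishes by enzymatic harvest. The labels list 17 samples. Bulk RNA sequencing has 3 libraries per day and single-cell RNA sequencing has 1 library per day, so 12 samples carried values here. The other 5 samples, 3 control and 2 Cited2 knockout libraries from cells of embryonic day 16.5, were not analysed here. Groups and replicate numbers were taken from the sample titles. No label says that the libraries of a day came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

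The bulk table holds RPKM (reads scaled to the length of the transcript and to the mapped reads of the library), deposited by the authors with each library in its own column, per the file headers. The libraries were made with Ion Torrent Proton protocols, per the labels' protocols. The tool that produced this table is not given in the sources used here. The submitters' processing notes list Cell Ranger, FastQC, Trim Galore 0.6.4, kallisto 0.46.0 and DESeq2 1.26 with the build GRCm38, without roles. The single-cell matrices hold UMI counts for all 737280 barcodes of the barcode list, deposited by the authors without a filter for cells. They come from Cell Ranger 3.0.2 per the file headers. Genes are given there by identifier only, and 45143 of the 46078 identifiers received a symbol from the GENCODE M21 reference tables. The protein table gives, per the file headers, the ratio of the medium and of the heavy label to the light label, which stand for day 1 and day 3 over day 0, with a p-value, an error factor and a number of peptides from the authors. How these were computed is not given in the sources used here, and no replicate columns are present. The authors' deposited table of cluster markers gives an average log fold change, used here as a score since the base of the log is not stated, the fraction of cells with each gene, p-values over cells and 12 cluster numbers. Only its gene ranks were used, and its p-values were not.

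The design foresaw read counts or normalized values. The bulk table turned out to hold RPKM, so limma was used with an intensity trend on log2(RPKM + 1). A fold change on this scale understates the change of low genes. All 9 libraries entered 1 fit, without a block for the replicate number. Of 53715 features, the 11559 with RPKM above 1 in at least 3 libraries were tested. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Genes called between day 0 and day 1 and again, in the opposite direction, between day 1 and day 3 are described as highest or lowest at day 1. RPKM values of a gene are whole multiples of the value of 1 read, which gave back the library totals. With a tolerance of 0.001, 92.7% of the genes with a length in the annotation came out whole in every library, and a search for the length that makes all 9 values whole gave reads for all 11559 tested genes. These equalled the reads from the annotation's length for 99.9% of 9169 genes that have both. The recovered totals were 3496693 to 5600779 mapped reads. Replicate pairs differed by more than sampling noise (chi-square per gene 2.80 to 6.50), so no library was counted as a copy of another, and their log2 values correlated with Pearson's r of 0.955 to 0.971 across genes.

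Gene lists, cell type markers, tests and the rule for named genes were fixed before the data were examined. The rule names, for each comparison, 20 key genes of osteoclast biology whatever their result, the 8 largest rises and 8 largest falls among changed genes whose replicate values do not overlap between the days and whose mean in the higher group is at least the median of the tested genes (4.66 RPKM), and up to 2 rises and 2 falls in each list. For genes highest or lowest at day 1 it names the 6 with the largest smaller change. The text gives a selection of these, and some are not reported here. There were 32 lists, of which 25 had at least 5 tested members and were compared with all other genes by camera with a preset correlation of 0.01. They cover osteoclast resorption, fusion and transcription factors, negative regulators, V-ATPase, lysosome, metabolism (respiratory chain, TCA cycle, glycolysis, serine and cholesterol), ribosome biogenesis, cell cycle and its inhibitors, antigen presentation, interferon, cytokines, immediate early and stress genes, and markers of macrophages, monocytes, neutrophils, myeloid progenitors, B cells, T or NK cells, mast cells or basophils, eosinophils, erythroid cells, megakaryocytes, stromal cells and endothelium. Where a list was called, camera was repeated with a correlation estimated from the libraries. The 25 lists were also tested with fry.

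In each single-cell library, barcodes were called cells when their UMIs reached 0.1 of the 99th percentile of the top 3000 barcodes, which came to 2501, 3976 and 5809 UMIs at days 0, 1 and 3, with at least 500 genes and at most 10% mitochondrial UMIs. This left 1767, 2406 and 1789 cells. Scrublet marked 20 of 5982 cells (0.334%) as doublets, too few for a working caller, so doublets remain possible. Counts were scaled to 10000 per cell, 2000 variable genes, 30 principal components and 15 neighbours were used, and Leiden clustering at a resolution of 0.6 gave 14 clusters without integration, since day and library are the same. A cluster received a cell type name from the fixed markers when at least 3 of them were raised 1.5-fold and seen in at least 25% of its cells. At least 1 also had to stand among its top 10 genes by fold, with fewer there of every other type. No other type could have more than 0.5 times as many markers raised and seen. These limits were chosen after the clusters had been seen. Levels are summed UMIs as CPM, that is, scaled to the total UMIs of the same cells. With 1 library per day no test was made. Intervals are 95% exact Poisson or exact Clopper-Pearson intervals and cover counting error only.

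Both procedures were tested on simulated data. With 11189 genes in the step, limma recovered 19.1%, 55.1%, 87.2% and 91.7% of genes changed 1.5-, 2-, 4- and 8-fold between day 1 and day 0, and 8.33% of its calls were false. Between day 3 and day 1 the shares were 27.7%, 46.9%, 85.1% and 91.7%, with 15.5% of calls false. Simulated genes highest or lowest at day 1 were recovered for 55.1% and 62.4%. In this simulation 10973 of the 11189 genes were unchanged, whereas 3884 genes were called between day 1 and day 0 in the real data. Recovery and the share of false calls depend on how many genes change, so these values need not hold there. In simulated single-cell libraries of 600 cells, shares of 2%, 10% and 30% osteoclast-like cells were recovered as 2%, 10% and 30%. These cells were drawn from the summed profiles of the clusters found here, without variation within a cluster. Their recovery was therefore easy and says little about real cells.

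Alternatives planned for the bulk comparisons were quantile normalization, no low-value filter, limma without trend, a replicate block, a pseudocount of 0.1, a log2 fold change of at least 1, only the compared groups in the fit, and leaving out each replicate. Chosen after seeing the data were edgeR on the recovered reads, centring each library on its median gene, and leaving out day 1 libraries 2 and 3. For the cells the alternatives were a doubled UMI minimum, a mitochondrial limit of 5%, doublets kept and Leiden resolutions of 1.0 and 0.3. Removal of the highest doublet scores, clustering without cell cycle genes and thinning to 4000 UMIs were added after seeing the data. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16. Positions are from GENCODE M21 on GRCm38.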

Results

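Osteoclast formation was followed at 3 times, day 0, day 1 and day 3 of RANKL, to ask in which steps marrow-derived macrophage precursors become osteoclasts. Bulk RNA was sequenced in 3 libraries per day. Mapped reads were 5600779, 4556222 and 3929347 at day 0, 4811428, 4488382 and 3496693 at day 1, and 4257373, 3539852 and 3738659 at day 3. The share of mapped reads on genes whose reads could be recovered with the annotation's length was 41.1% to 46.3% in 7 libraries and 34.7% and 34.8% in day 1 libraries 2 and 3. Single cells were sequenced in 1 library per day, with a median of 8063, 16629 and 21754 UMIs per cell at days 0, 1 and 3. Proteins were compared between the same days by isotope ratios. On GRCm38, the marker genes Acp5 and Ctsk lie on chromosome 9 (22126727 to 22135711) and chromosome 3 (95499256 to 95509362). The regulator Nfatc1 lies on chromosome 18 (80606205 to 80713071). Bulk changes are log2 fold changes on the log2(RPKM + 1) scale with their standard errors, and levels are mean RPKM ± SD (n = 3 libraries).

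The comparison of day 1 with day 0 asks what changes over the first day of RANKL. No culture with M-CSF alone was sampled at day 1 or day 3. Effects of RANKL therefore cannot be told apart from those of longer culture, here and in the comparisons below. Genes of bone resorption were among the largest rises. Acp5, which encodes tartrate-resistant acid phosphatase, went from 3.06 ± 0.654 to 295 ± 51.5 RPKM (SD, n = 3), a change of 6.18 ± 0.17 (limma adjusted p = 8.45e-09). Ctsk, the collagen-degrading protease cathepsin K, went from 4.06 ± 0.303 to 255 ± 51.4 (5.64 ± 0.15, adjusted p = 8.45e-09). Nfatc1, the master transcription factor of osteoclasts, rose by 2.94 ± 0.12 to 39.3 ± 4.38 RPKM (adjusted p = 5.52e-08). Over the same day interferon regulatory factor Irf8, a brake on osteoclast formation, fell by 2.75 ± 0.17, from 13.2 ± 0.855 to 1.15 ± 0.462 RPKM. The chemokine gene Ccl2 fell from 207 ± 28.8 to 0.653 ± 0.325 RPKM.

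Other large rises from day 0 to day 1 were Jdp2, an AP-1 family factor (4.74 ± 0.15), Atp6v0d2, a proton pump subunit of osteoclasts (4.21 ± 0.20), the sodium-proton exchanger Slc9b2 (4.17 ± 0.16) and the protease Mmp9 (3.92 ± 0.20). The fusion genes Dcstamp (3.74 ± 0.20) and Ocstamp (3.20 ± 0.12) rose too, as did the proteoglycan Sdc1 (3.80) and the signalling adaptor Traf1 (3.74). Besides Ccl2, the largest falls were the chemokine Ccl7 (-6.32), the transglutaminase F13a1 (-5.11), the platelet factor Pf4 (-5.01) and the endocytic adaptor Dab2 (-4.78). They were followed by the inhibitor of differentiation Id1 (-4.72), the Fc receptor Fcgr1 (-4.64) and the ribonuclease Rnase4 (-4.59). Itgb3, the integrin beta 3 chain with which osteoclasts attach to bone, fell by 0.78 ± 0.10 to 2.52 ± 0.0795 RPKM. Csf1r, the M-CSF receptor, fell by 0.96 ± 0.15, from 182 ± 11.3 to 93.8 ± 17.3. Bcl6 (-1.31) and Cd74, the invariant chain of antigen presentation (-1.63), also fell, and the dendritic cell integrin Itgax rose (0.79 ± 0.14), although in the single cells it was lower at day 1 (3.39 CPM) than at day 0 (5.26). Cited2, a transcriptional co-regulator that the study examined by knockout, rose from 3.79 ± 0.981 to 6.70 ± 0.689 RPKM (0.70 ± 0.19, adjusted p = 0.0152), a call that ended without day 0 library 3 or without day 1 libraries 2 and 3. Mki67, a proliferation marker, stood at -0.44 ± 0.15 (adjusted p = 0.0487), and its call ended under several alternatives, quantile normalization among them. Not called were Tnfrsf11a, which encodes the RANKL receptor RANK (0.15 ± 0.11, adjusted p = 0.322), Fos (0.45 ± 0.17, adjusted p = 0.0694), Myc (-0.38) and the calcitonin receptor Calcr (0.14). Fos and Tnfrsf11a passed with edgeR (adjusted p = 0.00108 and 0.0391).

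**Figure D1:**
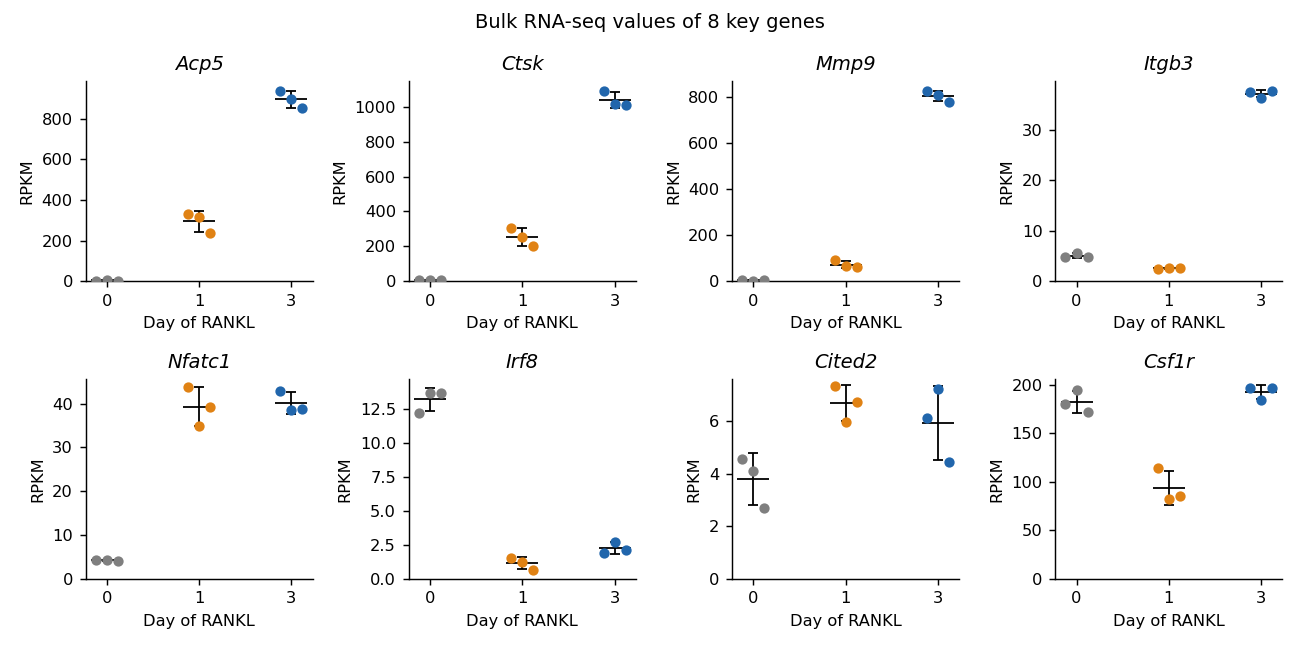
Bulk RPKM of 8 key genes (vertical axis) at day 0, day 1 and day 3 of RANKL (horizontal axis), with each of the 3 libraries per day as a point and bars for the mean and SD. Acp5 goes from a mean of 3.06 RPKM at day 0 to 295 at day 1 and 897 at day 3, while Irf8 goes from 13.2 to 1.15 and 2.26.

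Among the fixed lists, osteoclast resorption genes rose in 12 of 15 tested members by day 1 and fell in 2 (12 and 2 adjusted over the list alone, adjusted p = 2.38e-08, adjusted p = 0.104 with an estimated correlation). The falls included Ckb, creatine kinase B (-0.58). Of 18 fusion, receptor and adhesion genes 10 rose, such as the kinase Src (3.59), and 5 fell, such as the lipid receptor Trem2 (-1.73) (10 and 5 adjusted over the list alone, adjusted p = 0.00551, adjusted p = 0.354 with an estimated correlation). Of 19 osteoclastogenic transcription factors 10 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 0.000168, adjusted p = 0.328 with an estimated correlation). Negative regulators of osteoclast formation fell in 10 of 13, led by Id1 and Id3 (-4.05), while Tnfaip3, an inhibitor of NF-kappaB signalling, rose (0.75) (1 and 10 adjusted over the list alone, adjusted p = 6.58e-07, adjusted p = 0.0903 with an estimated correlation).

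Part of the genes of mitochondrial energy metabolism rose. In the respiratory chain and ATP synthase list 35 of 76 rose and 1 fell, with examples Cyc1 (1.11 ± 0.17) and Sdhd (0.99 ± 0.17) (42 and 1 adjusted over the list alone, adjusted p = 8.43e-08, adjusted p = 0.210 with an estimated correlation). Of 21 TCA cycle genes 11 rose, and 18 with edgeR, such as Pdhb (1.15), with 0 falls (14 and 0 adjusted over the list alone, adjusted p = 1.60e-05, adjusted p = 0.354 with an estimated correlation). V-ATPase subunits, which acidify lysosomes and the resorption space, rose in 7 of 18 (12 with edgeR) and fell in 2, with Tcirg1 at 1.38 and Atp6v0a1 at -2.42 (7 and 2 adjusted over the list alone, adjusted p = 0.00182, adjusted p = 0.354 with an estimated correlation). Ribosome biogenesis genes rose in 8 of 27 and in 19 with edgeR, Npm1 among them (0.81) (6 and 0 adjusted over the list alone, adjusted p = 0.000132, adjusted p = 0.372 with an estimated correlation). Cholesterol synthesis genes fell in 21 of 22, such as Insig1 (-2.11) and Fdps (-1.71) (0 and 21 adjusted over the list alone, adjusted p = 4.62e-10, adjusted p = 0.0909 with an estimated correlation). Lysosomal genes fell in 18 of 25, with the proteases Lgmn (-3.16) and Ctsb (-2.31), and Cd63 rose (0.61) (1 and 18 adjusted over the list alone, adjusted p = 1.23e-07, adjusted p = 0.210 with an estimated correlation). Unfolded protein and stress genes fell in 14 of 18 (0 and 16 adjusted over the list alone, adjusted p = 8.54e-07, adjusted p = 0.210 with an estimated correlation). S phase genes fell in 10 of 38, Pcna among them (-1.27) (0 and 10 adjusted over the list alone, adjusted p = 0.00860, adjusted p = 0.556 with an estimated correlation). The glycolysis list (1 rose and 1 fell of 17, 5 rises with edgeR, adjusted p = 0.616) and the serine and one-carbon list (5 rose and 1 fell of 11, 7 rises with edgeR, adjusted p = 0.0576) were not called. Neither were G2 and M phase genes (4 rose and 2 fell of 42, 11 rises with edgeR, none adjusted over the list alone, adjusted p = 0.453) or cyclin-dependent kinase inhibitors (1 rose and 3 fell of 7, adjusted p = 0.208).

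Markers of macrophages fell in 23 of 24, such as the scavenger receptor Stab1 (-4.08) (0 and 23 adjusted over the list alone, adjusted p = 3.56e-20, adjusted p = 0.0582 with an estimated correlation). Monocyte markers fell in 9 of 10, such as the chemokine receptor Ccr2 (-3.67) (0 and 9 adjusted over the list alone, adjusted p = 4.04e-07, adjusted p = 0.0817 with an estimated correlation). Antigen presentation genes fell in 8 of 11 and 1 rose (1 and 9 adjusted over the list alone, adjusted p = 0.000111, adjusted p = 0.104 with an estimated correlation). Interferon response genes fell in 9 of 13 (0 and 11 adjusted over the list alone, adjusted p = 6.69e-05, adjusted p = 0.0582 with an estimated correlation). Cytokines and chemokines fell in 8 of 10, while Il1rn (1.61) and Ccl9 rose (2 and 8 adjusted over the list alone, adjusted p = 3.78e-05, adjusted p = 0.157 with an estimated correlation). Immediate early genes, which respond to cell handling, fell in 12 of 19, such as Atf3 (-3.82) and Egr1 (-3.70), and the heat shock gene Hspa1b rose (2.21), with 4 rises by edgeR (2 and 12 adjusted over the list alone, adjusted p = 9.00e-06, adjusted p = 0.184 with an estimated correlation). Markers of other marrow cells moved at the same time. Neutrophil genes fell in 10 of 11, such as Mmp8 (-3.34), with a rise only of Mmp9, which the resorption list also holds (1 and 10 adjusted over the list alone, adjusted p = 7.30e-06, adjusted p = 0.0817 with an estimated correlation). All 6 tested progenitor genes fell, Elane by 1.52 (0 and 6 adjusted over the list alone, adjusted p = 0.000789, adjusted p = 0.0817 with an estimated correlation). So did 3 of 6 megakaryocyte genes, Pf4 among them (0 and 3 adjusted over the list alone, adjusted p = 0.0434, adjusted p = 0.311 with an estimated correlation). Pf4 is not particular to megakaryocytes here. In the single cells described below, 95.6% of the cells in the largest day 0 cluster, led by Wfdc17, Ccl7 and Ccl2, had a Pf4 UMI. In lists too small for camera, 3 of 4 B cell genes fell and Blnk rose, and 3 of 4 erythroid genes fell, with Hba-a2 at -4.57. Among eosinophil genes 2 of 3 fell, and the 3 stromal genes were not called. No gene of the T or NK cell, mast cell or basophil and endothelial lists passed the filter.

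Between day 0 and day 1, limma called 3884 of 11559 genes, 1609 that rose and 2275 that fell, so that 41.4% of called genes rose. That share depends on the scaling, being 51.6% after quantile normalization (2377 rose and 2227 fell) and 54.0% with edgeR on the recovered reads (2669 and 2278). It was 55.4% with each library centred on its median gene (2573 and 2068) and 54.4% without day 1 libraries 2 and 3 (1611 and 1349, with the lone day 1 library assumed to vary like the others). Camera called 21 of the 25 lists, 7 up and 14 down, and none with an estimated correlation, while fry called 21.

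By day 3 the resorption program stood well above its day 0 level. Against day 0, Acp5 had changed by 7.80 ± 0.17 to 897 ± 43.1 RPKM (SD, n = 3, adjusted p = 1.29e-09), Ctsk by 7.69 ± 0.15 to 1039.6 ± 46.7 and Mmp9 by 7.41 ± 0.20 to 803 ± 23.5. Calcr, near 0 at day 0 (0.0187 ± 0.0324 RPKM), reached 7.55 ± 1.04 (3.06 ± 0.15), and Itgb3, lower at day 1, reached 37.2 ± 0.716 (2.66 ± 0.10). Irf8 remained below day 0 (-2.13 ± 0.17), whereas Csf1r (0.08 ± 0.15, adjusted p = 0.702) and Cd74 (0.12 ± 0.18, adjusted p = 0.647) were not called.

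Also higher at day 3 than at day 0 were the metallothionein Mt3 (5.95 ± 0.17), Slc9b2 (5.62), Atp6v0d2 (5.47), Dcstamp (4.87) and Ocstamp (4.38). The same held for Nfatc1 (2.97), Itgax (2.51) and Fos (0.86, adjusted p = 0.00332). The histone gene Hist1h4m rose by 5.88 ± 1.51 and is listed at 0 at day 0. It belongs to a family of near-identical copies that can share reads. Ccl7, listed at 0 in all day 3 libraries, fell by 6.64, Ccl2 by 6.59, and F13a1 by 5.56. Fcgr1 fell by 4.61, Pf4 by 4.60, the beta-globin gene Hbb-bs by 4.51, the chemokine Ccl4 by 4.40 and Fcrls by 4.16. Mki67 fell (-0.71 ± 0.15, adjusted p = 0.00444). Bcl6 fell by 0.49 with a call that ended without the low-value filter. Cited2 stood at 5.94 RPKM (0.54 ± 0.19, adjusted p = 0.0495), a call that ended with edgeR (adjusted p = 0.0664) and most other alternatives. Tnfrsf11a (0.27, adjusted p = 0.0735) and Myc (-0.06) were not called.

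All 15 resorption genes were higher at day 3 than at day 0 (15 adjusted over the list alone, adjusted p = 1.33e-16, adjusted p = 0.0437 with an estimated correlation). So were 13 of 18 fusion, receptor and adhesion genes, while 3 were lower, Adam8 (-0.88) and Trem2 among them (14 and 3 adjusted over the list alone, adjusted p = 2.71e-08, adjusted p = 0.104 with an estimated correlation). Among transcription factors 11 of 19 rose, with the mitochondrial co-activator Ppargc1b at 3.00, and 1 fell (11 and 1 adjusted over the list alone, adjusted p = 4.06e-05, adjusted p = 0.249 with an estimated correlation). In the respiratory chain and ATP synthase list 66 of 76 genes rose and 0 fell, such as Uqcr10 (1.63 ± 0.12) and Cyc1 (1.65 ± 0.17) (70 and 0 adjusted over the list alone, adjusted p = 6.20e-18, adjusted p = 0.0775 with an estimated correlation). TCA cycle genes rose in 19 of 21, such as Mdh2 (1.72) (20 and 0 adjusted over the list alone, adjusted p = 2.85e-09, adjusted p = 0.196 with an estimated correlation). V-ATPase subunits rose in 15 of 18 with 1 fall (15 and 1 adjusted over the list alone, adjusted p = 1.72e-08, adjusted p = 0.144 with an estimated correlation). The lysosome list split, with 6 rises, Cd63 at 1.61, and 10 falls, Lgmn at -2.09, among 25 (8 and 10 adjusted over the list alone, adjusted p = 0.173, not called).

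**Figure D2:**
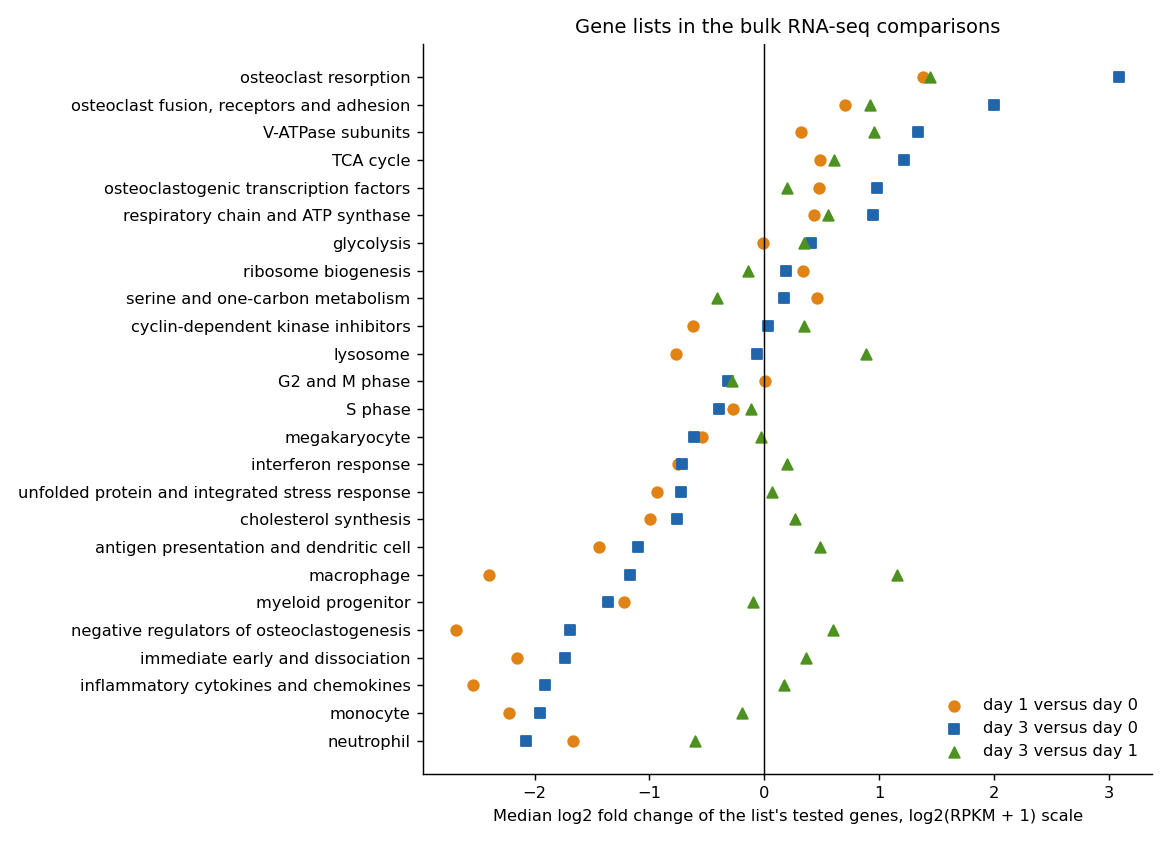
Median log2 fold change of the tested genes of each fixed list (horizontal axis, log2 of RPKM + 1) for day 1 versus day 0, day 3 versus day 0 and day 3 versus day 1, drawn as points without error bars. Resorption genes have medians of 1.38, 3.09 and 1.45, and macrophage markers -2.40, -1.17 and 1.16.

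Cholesterol synthesis genes were lower at day 3 than at day 0 in 17 of 22, such as Fdps (-1.48) (0 and 17 adjusted over the list alone, adjusted p = 4.76e-10, adjusted p = 0.0775 with an estimated correlation). Negative regulators were lower in 10 of 13 and higher in 2 (3 and 10 adjusted over the list alone, adjusted p = 2.17e-06, adjusted p = 0.0775 with an estimated correlation). Unfolded protein and stress genes fell in 13 of 18 (0 and 13 adjusted over the list alone, adjusted p = 1.08e-07, adjusted p = 0.161 with an estimated correlation). S phase genes fell in 14 of 38 and in 28 with edgeR (0 and 14 adjusted over the list alone, adjusted p = 1.08e-06, adjusted p = 0.317 with an estimated correlation). G2 and M phase genes fell in 11 of 42 and in 23 with edgeR (0 and 10 adjusted over the list alone, adjusted p = 1.69e-05, adjusted p = 0.361 with an estimated correlation). Macrophage markers fell in 17 of 24 (0 and 17 adjusted over the list alone, adjusted p = 8.26e-11, adjusted p = 0.0530 with an estimated correlation). Antigen presentation genes fell in 7 of 11 with 1 rise (1 and 7 adjusted over the list alone, adjusted p = 0.00397, adjusted p = 0.161 with an estimated correlation). Cytokines and chemokines fell in 8 of 10 with 2 rises (2 and 8 adjusted over the list alone, adjusted p = 4.60e-06, adjusted p = 0.104 with an estimated correlation). Immediate early genes fell in 11 of 19 with 4 rises (4 and 11 adjusted over the list alone, adjusted p = 1.92e-05, adjusted p = 0.161 with an estimated correlation). Monocyte genes fell in 9 of 10 (0 and 9 adjusted over the list alone, adjusted p = 2.85e-09) and interferon response genes in 8 of 13 (0 and 8 adjusted over the list alone, adjusted p = 0.000133). Neutrophil genes fell in 10 of 11 with Mmp9 alone rising (1 and 10 adjusted over the list alone, adjusted p = 1.72e-08) and progenitor genes in 6 of 6 (0 and 6 adjusted over the list alone, adjusted p = 3.48e-05). These 4 lists and the resorption list were the 5 that camera still called with an estimated correlation (adjusted p = 0.0437 each). Megakaryocyte genes fell in 3 of 6 (0 and 3 adjusted over the list alone, adjusted p = 0.0110, adjusted p = 0.174 with an estimated correlation). Glycolysis (7 rose and 2 fell of 17, adjusted p = 0.0892) and serine and one-carbon metabolism (1 rose and 5 fell of 11, adjusted p = 0.165, a median of 0.18 against a downward camera direction) were not called. Nor were ribosome biogenesis (4 rose of 27, 7 with edgeR, adjusted p = 0.173) and kinase inhibitors (2 rose and 3 fell of 7, adjusted p = 0.515, a median of 0.03 against a downward camera direction). Of the lists too small for camera, 3 of 3 tested stromal genes rose, such as Col1a1, a collagen of osteoblasts and fibroblasts, and Sparc (1.61). Only 3 of the 17 stromal genes passed the filter. A gene low at days 0 and 1 can pass it through the day 3 libraries alone, so this count says little about the list. In the others 3 of 4 erythroid genes fell, 2 of 4 B cell genes fell and Blnk rose, and the eosinophil gene Ccr3 (1.30) rose while Prg2 fell.

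For day 3 versus day 0, 3854 genes were called by limma, 2319 up and 1535 down (60.2% up). The share of rises was 47.5% after quantile normalization (2036 and 2249), 51.1% with edgeR (2342 and 2239) and 46.3% with centring (1993 and 2315), so which direction prevailed depends on the scaling. Camera called 20 lists, 6 up and 14 down, and fry 19.

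The comparison of day 3 with day 1 asks what distinguishes maturing cultures from those after a single day of RANKL. Attachment and late osteoclast genes rose: Itgb3 by 3.44 ± 0.10 (adjusted p = 7.26e-08), Oscar by 3.48 ± 0.16 and Calcr by 2.92 ± 0.15. The sialic acid receptor Siglec15 rose by 3.03 ± 0.20, Mmp9 by 3.49 ± 0.20, and Ckb from 38.5 ± 6.03 to 401 ± 14.2 RPKM (3.36 ± 0.13). The largest rises were Mt3 (4.19 ± 0.17), the aldo-keto reductase Akr1c18 (4.11 ± 0.14) and the lactate dehydrogenase subunit Ldhb (3.72 ± 0.30). Ctsk (2.04) and Acp5 (1.62, adjusted p = 0.000163) rose further, while Nfatc1 was not called (0.03 ± 0.12, adjusted p = 0.887). After quantile normalization Nfatc1 was called down (-0.28, adjusted p = 0.0426). Several macrophage genes rose from their day 1 level, among them Csf1r (1.05 ± 0.15), Cd74 (1.75), the lipoprotein gene Apoe (2.38) and the complement gene C1qb (2.12).

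Itgax (1.73) and Ocstamp (1.18) rose as well, as did Atp6v0d2 (1.26), Dcstamp (1.13) and Bcl6 (0.81), whose calls ended without day 1 libraries 2 and 3. Irf8 rose by 0.62 ± 0.17 (adjusted p = 0.0270), a call lost after quantile normalization, centring and leaving out either of those libraries. The largest fall was Phgdh, the entry enzyme of serine synthesis (-1.79 ± 0.19, adjusted p = 0.000186). It was followed by the transfer RNA gene mt-Tl2 (-1.66, not called by edgeR), the protease inhibitor Serpinb1a (-1.37) and the serotonin transporter Slc6a4 (-1.36). Next came AC099934.2 (-1.29), Raver1_1 (-1.28), the serine synthesis enzyme Psat1 (-1.16) and the neutrophil granule gene Camp (-1.14, not called without day 1 libraries 2 and 3). Fos (0.40), Cited2 (-0.17), Tnfrsf11a (0.13), Myc (0.32) and Mki67 (-0.28) were not called, although Mki67 fell by 0.47 with edgeR (adjusted p = 0.00303).

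From day 1 to day 3 all 15 resorption genes rose (15 and 0 adjusted over the list alone, adjusted p = 3.51e-15, adjusted p = 0.111 with an estimated correlation), 14 of them with edgeR. So did 16 of 18 fusion, receptor and adhesion genes (17 and 0 adjusted over the list alone, adjusted p = 2.86e-13, adjusted p = 0.126 with an estimated correlation). V-ATPase subunits rose in 16 of 18 (17 and 0 adjusted over the list alone, adjusted p = 5.17e-10, adjusted p = 0.184 with an estimated correlation). Lysosomal genes rose in 23 of 25, such as Ctsd and Hexa (1.36) (25 and 0 adjusted over the list alone, adjusted p = 5.97e-14, adjusted p = 0.184 with an estimated correlation). Respiratory chain genes rose in 43 of 76, Cox6a1 by 0.96 (55 and 0 adjusted over the list alone, adjusted p = 4.75e-11, adjusted p = 0.205 with an estimated correlation), though in only 18 after quantile normalization. TCA cycle genes rose in 13 of 21, Cs by 0.97 (16 and 0 adjusted over the list alone, adjusted p = 3.63e-05, adjusted p = 0.441 with an estimated correlation). Macrophage markers rose in 21 of 24 (21 and 0 adjusted over the list alone, adjusted p = 1.69e-14, adjusted p = 0.111 with an estimated correlation). Negative regulators rose in 8 of 13, with Id3 at 1.59 (8 and 0 adjusted over the list alone, adjusted p = 5.98e-05, adjusted p = 0.184 with an estimated correlation). Antigen presentation genes rose in 4 of 11 (6 and 0 adjusted over the list alone, adjusted p = 0.0119, adjusted p = 0.276 with an estimated correlation). Immediate early genes rose in 5 of 19 (8 and 0 adjusted over the list alone, adjusted p = 0.0150, adjusted p = 0.441 with an estimated correlation).

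G2 and M phase genes fell in 10 of 42 (0 and 12 adjusted over the list alone, adjusted p = 3.00e-14, adjusted p = 0.234 with an estimated correlation), and in 31 with edgeR. Serine and one-carbon genes fell in 4 of 11 and in 9 with edgeR (0 and 4 adjusted over the list alone, adjusted p = 1.31e-06, adjusted p = 0.246 with an estimated correlation). Ribosome biogenesis genes fell in 2 of 27 and in 9 with edgeR, Npm1 among them (-0.72) (0 and 1 adjusted over the list alone, adjusted p = 3.63e-05, adjusted p = 0.441 with an estimated correlation). The S phase list was called down with 1 rise and 1 fall among 38 members, and 13 falls with edgeR (0 and 0 adjusted over the list alone, adjusted p = 0.000155, adjusted p = 0.481 with an estimated correlation). The monocyte list was called down with 1 of each among 10, and 5 falls with edgeR (adjusted p = 0.0382, adjusted p = 0.410 with an estimated correlation). The neutrophil list had 6 falls and 3 rises among 11, Lyz1 and Mmp9 among the rises (3 and 6 adjusted over the list alone, adjusted p = 0.00357, adjusted p = 0.184 with an estimated correlation). Not called were transcription factors (4 rose of 19, adjusted p = 0.491, against 1 rise and 4 falls after quantile normalization), glycolysis (4 rose of 17, 2 falls with edgeR, adjusted p = 0.108) and cholesterol synthesis (5 rose of 22, adjusted p = 0.154). Nor were kinase inhibitors (2 rose of 7, Cdkn1a at 0.93, adjusted p = 0.156) and interferon response (2 rose of 13, adjusted p = 0.501). The same holds for cytokines (3 rose of 10, adjusted p = 0.501), stress genes (3 rose and 1 fell of 18, 3 falls with edgeR, adjusted p = 0.652, a median of 0.07 against a downward camera direction), progenitor genes (adjusted p = 0.108) and megakaryocyte genes (adjusted p = 0.509). B cell genes fell in 1 of 4, and erythroid genes were not called. Stromal genes rose in 3 of 3 tested, Col1a1 by 1.46, with the same limit that only 3 of 17 passed the filter. The eosinophil list's Ccr3 rose by 1.51.

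Limma called 2116 genes between day 1 and day 3, 1888 up and 228 down (89.2% up), and the median of all tested genes was 0.14. The median moved to -0.03 after quantile normalization, -0.02 with edgeR and -0.09 with centring, and to 0.01 without day 1 libraries 2 and 3. For the scalings the share of rises moved to 56.3% (1305 and 1011), 61.1% (1566 and 995) and 49.8% (1173 and 1183), so the small changes listed here are read against a shift of that size. Relative to the median of all tested genes, resorption genes still had a median of 1.31, lysosomal genes 0.75 and macrophage markers 1.02. Without day 1 libraries 2 and 3, 543 genes rose and 121 fell (81.8% up of 664). The count also fell more than 1.5-fold without day 1 library 2 (1348), day 3 library 1 (1318) or day 3 library 3 (1359). Camera called 16 lists, 10 up and 6 down, with none called under an estimated correlation, and fry 14.

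Some genes passed through an extreme at day 1. The genes named by the fixed rule include Apoe and 3 complement genes, which fell and then rose again. Apoe went from 258 ± 26.5 RPKM at day 0 to 46.9 ± 4.58 at day 1 and 250.0 ± 34.1 at day 3 (SD, n = 3). C1qa went from 56.0 to 13.3 and 59.1, C1qb from 253 to 14.6 and 67.0, and C1qc from 91.4 to 9.13 and 42.9. In the single cells their day 3 levels stayed below day 0, at 0.147 of it for C1qa, 0.0587 for C1qb, 0.107 for C1qc and 0.313 for Apoe. Beside them were the receptor gene Cd300ld and the prostaglandin-degrading enzyme Hpgd. In the opposite direction, the serotonin transporter Slc6a4 went from 0.269 to 5.77 and 1.56 RPKM and the glutathione transferase Gstt1 from 0.0555 to 5.69 and 2.46, with Bbs9, Serpinb1a, Mir99ahg and mt-Tl2 following the same course in bulk. The single cells did not share this course for every gene. Of 80 genes highest at day 1 in bulk with at least 50 UMIs, 71 were higher in the cells at day 1 than at day 0, and 69 were lower at day 3 than at day 1. In all, limma called 859 genes lowest and 103 highest at day 1. The imbalance depends on the scaling, with 643 and 537 genes after quantile normalization, 760 and 493 with edgeR, and 573 and 557 with centring. Lists of the same sizes that are independent would share 372 and 31.7 genes. Both contrasts use the same day 1 libraries. In a test chosen after seeing these counts, with 1 day 1 library in one contrast and the other 2 in the other, 314 to 717 genes were lowest at day 1, 2.17 to 2.78 times the overlap of independent lists. Of the 859 genes 717 were still called with edgeR, 634 after quantile normalization and 257 without day 1 libraries 2 and 3. The total was 1415 without day 1 library 1, 558 without day 1 library 2 and 570 without day 3 library 1, and genes highest at day 1 numbered 67 without day 3 library 1.

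Single cells showed how the captured cells divide into clusters. Shares are of barcodes called cells, and how many multinucleated osteoclasts were captured was not measured. At day 3, 459 of 1789 cells (25.7%, 95% interval 23.6 to 27.7) formed an osteoclast-like cluster whose leading genes were Mt3, Mmp9, Itgb3, Ckb and Oscar, against 1 of 1767 cells at day 0 (0.0566%) and 1 of 2406 at day 1 (0.0416%). Neutrophil-like cells made up 14.5% (12.9 to 16.3) of day 0 cells, 2.37% (1.80 to 3.06) at day 1 and 3.13% (2.37 to 4.05) at day 3. They were 13.4%, 1.55% and 1.52% with the minimum of UMIs doubled, which leaves no rise from day 1 to day 3. Macrophage-like cells, led by Cd5l, Vcam1 and C1qa, were 0.962%, 0.748% and 3.35% (2.57 to 4.30), but 0.377%, 0.388% and 0.483% with the minimum of UMIs doubled (their median was 8496.5 UMIs at day 3). This share does not count all macrophages. The unnamed clusters with 741 and 588 day 0 cells, described below, each had 8 macrophage markers raised, against 7 in the macrophage-like cluster. Further, 12 stromal-like cells were found at day 3 only (0.671%), where 0 cells at days 0 and 1 allow shares of up to 0.170% and 0.125% (one-sided 95% bounds). A cluster mostly of 1 library may be that library rather than a cell type, the osteoclast-like share restates the levels of the genes that define it, and depth differed between the days.

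The remaining cells were left unnamed and are described by their leading genes. At day 0 they were mostly in a Wfdc17, Ccl7 and Ccl2 cluster (741 cells, 41.9%) and a Ccl2 and Dab2 cluster (588 cells, 33.3%). By day 1 they lay in an Adig and Jdp2 cluster (773 cells, 32.1%), a Ube2c and Cenpf cluster of dividing cells (627, 26.1%), a Mybl2 and Rrm2 cluster of DNA synthesis (492, 20.4%) and a Cav1 and Vcan cluster (382, 15.9%). The Ube2c and Cenpf cluster and the Mybl2 and Rrm2 cluster held 0 day 0 cells. This does not mean that division began at day 1. Clusters were formed without integration, and the summed level of G2 and M phase genes, given below, was highest at day 0. At day 3 the Cav1 and Vcan cluster was the largest (647 cells, 36.2%, 33.9 to 38.4), while the Ube2c and Cenpf cluster held 201 cells (11.2%), the Adig and Jdp2 cluster 151 (8.44%) and the Mybl2 and Rrm2 cluster 92 (5.14%). Smaller clusters were led by Elane, Prtn3 and Mpo (4.70% of day 0 cells), by Mmp12 and Itgax (4.64% of day 3 cells) and by the antigen presentation genes H2-Aa and Cd74 (3.74% of day 0 cells). Of the top 30 genes of the osteoclast-like cluster, 17 were shared with cluster 7 in the authors' deposited table of markers, and of the macrophage-like cluster, 17 with cluster 10.

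**Figure D3:**
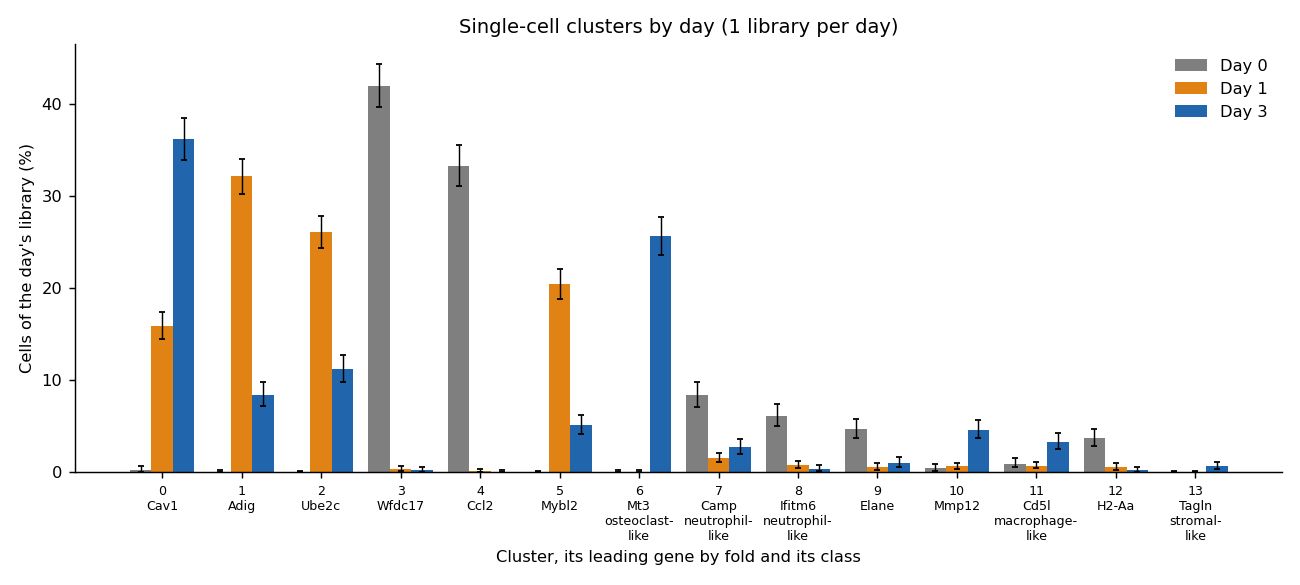
Percent of cells (vertical axis) in each of the 14 clusters at day 0, day 1 and day 3, with 95% exact Clopper-Pearson intervals that cover counting error only. The osteoclast-like cluster holds 0.0566%, 0.0416% and 25.7% of cells, and the neutrophil-like class falls from 14.5% to 3.13%.

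Summed over all cells of a day, Acp5 stood at 29.8 (27.2 to 32.6), 806 (797 to 814) and 2156 (2143 to 2170.5) CPM at days 0, 1 and 3 and Nfatc1 at 24.6, 256 and 286. Calcr had 0 UMIs at day 0 (up to 0.228) and 27.7 at day 3. Itgb3 dipped from 8.92 to 2.15 before reaching 148, and Irf8 went from 99.8 to 5.54 and 5.61. Cited2 was at 117 (112 to 123), 211 (206 to 215) and 202 (198 to 206), and Csf1r at 468, 241 and 459. The lists without tested bulk genes were low: T or NK cell genes at 43.2, 5.56 and 5.40, mast cell or basophil genes at 21.8, 4.26 and 4.46, and endothelial genes at 10.1, 4.65 and 4.13. G2 and M phase genes went from 3062 to 2527 and 1923.

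Within day 3, the osteoclast-like cells differed from the other 1330 cells also in genes outside the markers that named them, although all variable genes took part in the clustering. Their G2 and M phase genes stood at 349 (339 to 359) CPM against 2651 (2632 to 2670), and at 349 against 2647 when the cells were clustered without cell cycle genes. S phase genes stood at 599 against 2292 and Mki67 at 7.95 against 131. Irf8 was at 1.26 against 7.62. Respiratory chain genes stood at 59360 against 37456, TCA cycle genes at 5925 against 2051 and the mitochondrial genome at 38089 against 15960. Csf1r was at 772 (757 to 787) against 314 (308 to 320), Tnfrsf11a at 159 (152 to 166) against 109 (105 to 113), and Cited2 at 323 (313 to 333) against 146 (142 to 151), with 254 in the neutrophil-like cells and 180 in barcodes of few UMIs. Free RNA sets a background: Acp5 stood at 78.7 in neutrophil-like cells of day 3 (60.7% of those cells had a UMI at a median of 10627 UMIs, 26.8% after thinning to 4000) and at 1277 in barcodes of 10 to 100 UMIs.

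**Figure D4:**
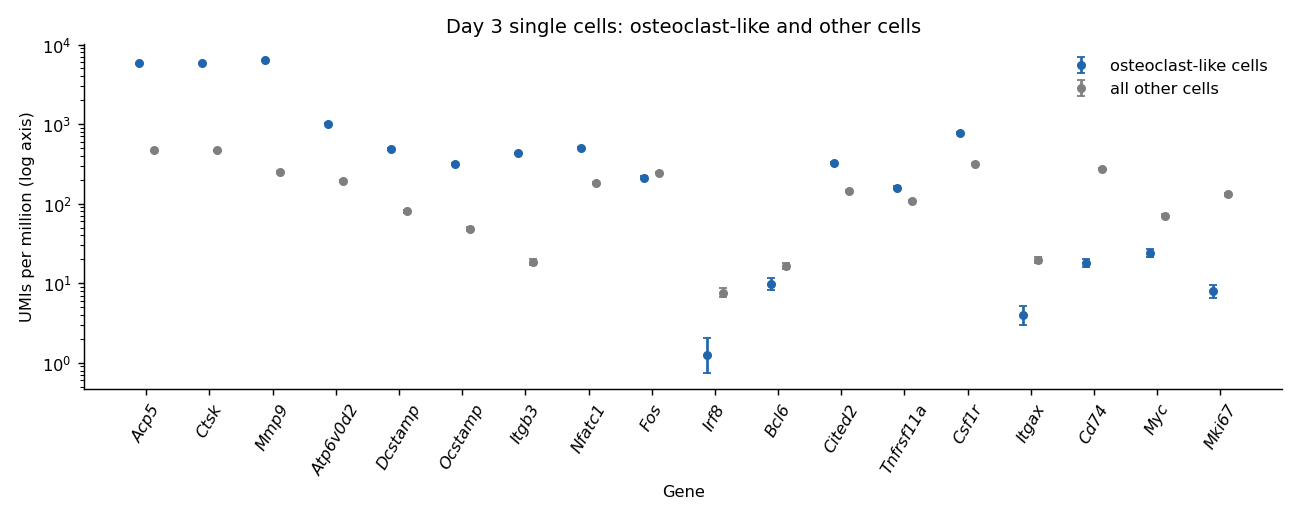
CPM (vertical log axis, UMIs scaled to the total) of key genes in osteoclast-like cells and in all other cells of day 3, with 95% exact Poisson intervals that cover counting error only. Cited2 stands at 323 and 146, and Irf8 at 1.26 and 7.62.

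Changes in bulk RNA and in summed single cells were compared across genes, which are not independent replicates. Pearson's r was 0.826 for day 1 versus day 0 (9987 genes, Spearman's rho 0.762), 0.812 for day 3 versus day 0 (10085 genes, 0.768) and 0.597 for day 3 versus day 1 (10111 genes, 0.564). Of the genes called in bulk, 94.5%, 94.0% and 93.2% had the same sign in the cells, and 94.6%, 94.1% and 88.9% relative to the medians. Of the 826 genes lowest at day 1 in bulk with at least 50 UMIs, 787 (95.3%) were higher at day 3 than at day 1 in the cells, as were 65.4% of 9285 other tested genes.

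At the protein level, the authors' deposited table lists 878 proteins, 690 of them mouse proteins with ratios. Day 3 over day 0, the authors' deposited table gives a ratio of 45.2 for Acp5 (authors' p = 0.00534, 6 peptides), 3.38 for Ckb (authors' p = 0.00895) and 2.38 for the ATP synthase subunit Atp5a1 (authors' p = 6.95e-05). In the authors' deposited table F13a1 stood at 0.193 (authors' p = 0.000636) and the neutrophil protein S100a9 at 0.115 (authors' p = 0.00326). All 19 respiratory chain and ATP synthase proteins of the authors' deposited table had day 3 ratios above the median of the table (1.17), with a median of 2.34, as did 8 of 9 TCA cycle proteins, while 0 of 4 neutrophil and 0 of 6 serine and one-carbon proteins did. In the authors' deposited table an authors' p under 0.05 was given for 3, 2, 1 and 0 of these proteins, in that order. Of the 19, Atp5d and Ndufa4 stood at the upper limit of 100 in the authors' deposited table, and Ndufs6 had 0 peptides. At day 1 the authors' deposited table has a median ratio of 2.04, and 120 ratios above 1 but 0 below 1 carry an authors' p under 0.05, so these ratios are read against that median. Lysosomal proteins lay above it in 7 of 10 in the authors' deposited table, with Ctsb at a ratio of 2.80 (authors' p = 0.000809) and Ctsd at 3.04 (authors' p = 0.0462). The RNA of Ctsb had a log2 fold change of -2.31, a ratio of 0.202. The protein ratios are 1.37 and 1.49 times the median, and no p is given for a difference from the median. Glycolysis proteins of the authors' deposited table lay above it in 7 of 9, although their RNA list was not called. In the authors' deposited table, 2 of 3 resorption proteins lay below it, with Ctsk at 0.707 (1 peptide, no p) while its RNA rose, and Acp5 lay above it at 8.72 (authors' p = 0.459, 6 peptides). Across proteins, the ratios of the authors' deposited table correlated with the bulk RNA change with a Pearson's r of 0.259 at day 1 (640 proteins, Spearman's rho 0.268) and 0.422 at day 3 (635 proteins, 0.363). Among genes called in bulk, 118 of 262 (45.0%) had the same sign as the authors' deposited table at day 1 and 179 of 243 (73.7%) at day 3. Relative to the medians, the shares were 66.0% and 74.1%.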

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

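The splits of the libraries and the 2 tests of the direction of change between day 1 and day 3 were chosen after the results were seen. RNA of osteoclast genes was also found in barcodes with too few UMIs to be called cells. Osteoclast marker genes, which no comparison of cells covers there, made up 1551 CPM (1366 to 1753) in day 1 barcodes of 10 to 100 UMIs and 4786 CPM (4541 to 5040) in those of day 3, against 137 (127 to 149) at day 0. They rest on 256, 1432 and 608 UMIs, and the difference was not tested, with 1 library per day. The pools of such barcodes were unlike. Day 0 had 60627 of them with 4425838 UMIs, day 1 had 6482 with 165100, and day 3 had 8647 with 299217.

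Exchanging libraries between days ended nearly all gene calls, while the highest other split still called many lists. For day 1 versus day 0, 1 of 10 splits, the real one, called as many as 3884 genes (highest other 1), and 1 of 10 as many as 21 lists (highest other 19). For day 3 versus day 0 the same was true of 1 of 10 splits for 3854 genes (highest other 0) and of 1 of 10 for 20 lists (highest other 18). For day 3 versus day 1 it was true of 1 of 10 for 2116 genes (highest other 2) and of 1 of 10 for 16 lists (highest other 13). With 10 splits a share below 0.05 cannot occur, so these numbers decide nothing about chance. Among 100 splits of all 9 libraries, 3 gave as many as 103 genes highest at day 1 (highest other 1021) and 2 as many as 859 lowest (highest other 911). The highest values come from a split that keeps a day whole, as 11 splits do, while the other 88 gave at most 2 and 0 genes.

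Most genes called between day 1 and day 3 rose (89.2%). The pattern depended on scaling to all mapped reads, since with edgeR, which scales on the reads of the tested genes, 61.1% rose. The role of the 2 day 1 libraries with few reads on tested genes cannot be told apart from the rest, because without them 81.8% of 664 called genes rose but the median of all tested genes moved from 0.14 to 0.01. Whether more genes rise than fall in the cells themselves was not tested, since no measure of RNA per cell exists here. Large rises do not turn on this choice, as Itgb3 rose by 3.44 with limma and by 3.70 with edgeR.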

How the results depend on the processing

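Alternatives with edgeR, centring, or without day 1 libraries 2 and 3, and for cells thinning, clustering without cycle genes and removal of the highest doublet scores, were chosen after seeing the data, as were 2 protein subsets. The planned Cited2 alternatives were not run, and the cause of the shifts below was not tested. Requiring a log2 fold change of at least 1 left 1348 (day 1 versus day 0), 1396 (day 3 versus day 0) and 451 (day 3 versus day 1) genes. Between day 3 and day 1, 1388 genes were changed with no low-value filter, 664 without day 1 libraries 2 and 3, and 1318 to 3030 with 1 replicate left out. Genes highest at day 1 numbered 537 with quantile normalization, 493 with edgeR, 557 with centring, 64 without day 1 libraries 2 and 3, and 67 to 101 with 1 replicate left out. Genes lowest at day 1 numbered 551 with no filter, 266 without those libraries, and 558 to 1415 with 1 replicate left out. With an estimated correlation 0, 5 and 0 lists were called in the 3 comparisons. A replicate block gave 3719, 3689 and 1952 genes, with same-number correlations of -0.128 to 0.133. Directions turned in these cases: Csf1r (day 3 versus day 0) -0.061 with quantile normalization and -0.030 with centring, Cd74 -0.0057 with quantile normalization. For day 3 versus day 1, Nfatc1 was -0.28 with quantile normalization (adjusted p = 0.0426), -0.16 with edgeR, -0.12 without day 1 libraries 2 and 3, -0.19 with centring, -0.049 without day 1 replicate 2 and -0.02 without day 3 replicate 1. It kept its sign without day 1 replicate 1 (0.11). Tnfrsf11a was -0.18, -0.060 and -0.10 with quantile normalization, edgeR and centring, and Myc -0.037 without day 1 libraries 2 and 3. With minimum UMIs doubled, macrophage-like cells were 0.377%, 0.388% and 0.483% at days 0, 1 and 3, and neutrophil-like cells 1.55% at day 1 and 1.52% at day 3. Neutrophil-like cells of day 0 were 18.8% at Leiden resolution 0.3 and 18.8% after thinning. Osteoclast-like cells of day 3 were 21.4% with at most 5% mitochondrial UMIs. Bulk and single-cell changes correlated at 0.867, 0.853 and 0.648 with at least 500 UMIs. Protein correlations were 0.353 and 0.594 for called genes, 0.128 and 0.862 for an authors' p under 0.05, and 0.355 at day 3 with limited ratios kept.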

Other observations

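The test of nuclear respiratory chain genes and the comparison with other genes that fell by day 1 were chosen after the result was seen. Cells that share a day also differ from each other. The Cav1 and Vcan cluster, which holds 382 cells at day 1 and 647 at day 3, has few osteoclast transcripts. At day 1 its Irf8 was 11.3 times as high as in the Adig and Jdp2 cluster, and at day 3 it stood at 5.59 CPM (4.39 to 7.02) against 0.788 (0.163 to 2.30), with 5.61 in all cells of that day. Acp5 stood at 136 CPM (127 to 145) against 1249 (1230 to 1268), Ctsk at 130 against 456, Nfatc1 at 105 against 325 and Jdp2, among the leading genes of the second cluster, at 113 against 454. At day 3 the gap remained, with Acp5 at 132 against 1578, while Cav1 itself, a scaffold of membrane caveolae, rose within the first cluster from 228 to 407.

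Osteoclast-like cells of day 3 differed in further genes and lists. Ribosome biogenesis genes stood at 1784 CPM against 3745 in the other cells, Myc at 23.9 against 71.0 and the cell cycle inhibitor Cdkn1a at 14.9 against 118. Serine and one-carbon genes stood at 289 against 472. V-ATPase subunits, by contrast, stood at 15530 against 4538, lysosomal genes at 11190 against 8373, cholesterol synthesis genes at 521 against 311 and eosinophil markers, which include Ccr3, at 80.5 against 13.9. The macrophage list stood at 1575 against 4979. Most C1qa transcripts came from few cells. At day 3, 76.6% of the C1qa UMIs, 46.3% of those of C1qc and 19.8% of those of C1qb lay in the 60 macrophage-like cells, against 13.2% of Apoe.

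Limma called 859 genes lowest at day 1. Scaling to all mapped reads is not the whole cause, since 83.5% of these genes were still called with edgeR. A return of the cells named macrophage-like at day 3 alone would leave the other cells low. Without those cells 94.6% of 826 genes were higher at day 3 than at day 1, against 95.3% with them (in all cells, 65.4% of other tested genes and 76.5% of 1268 genes that fell by day 1 and were not called afterwards). These 60 cells were 3.35% of day 3 cells, so their removal could change little. Unnamed clusters stayed in, such as the Cav1 and Vcan cluster with 15.9% of day 1 and 36.2% of day 3 cells. Changed shares of other cells, macrophages among them, therefore stay open. With separate day 1 libraries in the contrasts, the genes lowest at day 1 were still at least 2.17 times the overlap of independent lists. Both contrasts still used a common estimate of each gene's spread, which can raise the overlap. The part played by shared day 1 libraries therefore stays open. Only 257 of the 859 calls remained without day 1 libraries 2 and 3, so how many genes truly dip stays open.

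Mitochondrial UMIs were a median of 4.13% in osteoclast-like cells and 1.63% in the other cells of day 3, and 98 and 7 cells lay above 5%. Damaged cells that lost cytoplasmic RNA would pair a high share with few UMIs, and osteoclast-like cells above their median share held 0.662 times the UMIs of the rest (medians 22879 and 34570). The share is taken over the same UMIs, so a low total can go with a high share without damage. The other day 3 cells held a median of 19596 UMIs, below those 22879, and osteoclast-like cells above 5% held 19131.5. More respiratory chain expression from the nucleus too also meets its test, as the list stood 1.58 times higher in osteoclast-like cells than in the other cells. Both explanations stay open, and even the osteoclast-like cells at or below their median share had 3.22% mitochondrial UMIs. Doublets remain untested, because the doublet caller did not work here.

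A hypothesis about the Cav1 and Vcan cluster (cluster 0) was tested on values not seen when the test was written. If its low Acp5 and Nfatc1 at day 1 came from less RANK messenger RNA, Tnfrsf11a should be lower there. It stood at 117 CPM (109 to 126) against 114 (108 to 120), a ratio of 1.03. Less M-CSF receptor messenger RNA was not found either, as Csf1r stood at 319 against 261, a ratio of 1.22. Receptor protein and signalling were not measured, so they remain open. So do the levels of both messenger RNAs when RANKL was added, since these clusters held only 5 and 1 day 0 cells.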
